A study of Mus musculus with 4 samples.

How the data were processed

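The study measured trimethylation of lysine 4 on histone H3 (H3K4me3), a mark of active promoters, by ChIP-seq in mouse embryonic stem cells of the WW6 line. Per the labels' protocols, cells were transfected with a small interfering RNA against Kdm5b, an enzyme that removes methyl groups from H3K4, or with a control. The labels describe 4 samples, which are the H3K4me3 immunoprecipitate and the input of control cells and of knockdown cells, with 1 library each. The treatment label calls the control a mock construct, the protocol in the labels names a GFP control, and the authors' list names carry a scramble abbreviation, so the kind of control is not settled here. The list names also give the knockdown the prefix sh, so the kind of knockdown construct is not settled either. Per the labels' protocols, chromatin of formaldehyde-crosslinked cells was precipitated with 5 µg of antibody.

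Per the submitters' processing notes, reads were handled with Trim Galore 0.3.3, BWA, Picard 1.117 and MACS2 2.1.0.20140616, and the genome build is mm9. The order and settings of these tools, the calling threshold and the control given to the peak caller are not given in the sources used here. Peaks were called in each library of this study, without replicates. The lowest −log10 q in each of the authors' 8 deposited lists lies between 1.31 and 1.38, just above the value of 1.30 that corresponds to a q of 0.05. The authors also deposited 6 lists made from the data of other laboratories, named Kidder and Schmitz after the authors' own list names: an H3K4me3 control and knockdown list and a Kdm5b list for each. What is in those lists comes from the authors' list names and readme alone. No sample of this series stands behind them, and the readme does not give the roles of the pairs of source samples behind both Kidder H3K4me3 lists and the Schmitz Kdm5b list.

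Each deposited list gives a peak's position and 4 values at its summit, in the narrowPeak format of the authors' peak caller. The fold enrichment, as deposited by the authors, is a linear ratio of the scaled reads at the summit to the local background. The peak caller adds the same constant to both terms. Fold is therefore lower than the plain ratio of reads to background, most so where the background is low, as in the Kidder control list. The −log10 p and −log10 q at the summit are deposited by the authors and were used for thresholds, for ranking within a list and to recover reads. The deposited score is 10 times the −log10 q without its decimals and was not used further. These values are the authors' own and are used here to describe, rank or filter peaks within a list. The position of a summit was used for distances between peaks.

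The lists hold no read totals. The fold and the −log10 p together fix the background, the scaling of the immunoprecipitate and the whole number of reads at each summit, under the Poisson model of the peak caller. For each list, the scale and background were searched for the values that return the most deposited −log10 p values within 0.003. Between 91.7% and 100% of peaks in a list then had exactly 1 whole number of reads. In simulated lists based on the lengths of the 6 H3K4me3 lists, the reads were right for 100% of the peaks with 1 solution. Reads, scale and background were drawn from fixed ranges, and every simulated summit held more reads than the Kidder median summits of 4 and 6. The scale of the Schmitz control list and the backgrounds of the Kidder control and both Schmitz H3K4me3 lists lay below those ranges. Recovery at such values was therefore not tested. With the deposited p-values scrambled across peaks, only 3.16% to 10.4% could be matched. The depth of a library is given as reads per kb of the genome size assumed by the peak caller. It further assumes that the narrowest peak is as wide as the assumed fragment, so depth is an estimate and is used mainly as a ratio within a pair. The 3 Schmitz lists gave the same scaled background, 0.567 reads per kb.

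Overlap of at least 1 bp counted as shared. A peak with no such overlap in the other list of its pair was called control-only or knockdown-only. With 1 library per condition no test between the conditions of a pair was possible, and no p-value within a pair is given. Shares carry 95% exact Clopper-Pearson intervals, which cover counting error over peaks only and not the variation between cultures. Peaks are not replicates. Shares at Kdm5b peaks were set beside 10000 random lists of the same size from the same peak list, matched on decile of fold. They describe these libraries and are no test of the conditions. The same random lists could not be used for distances, because a shared peak is at distance 0 by construction. In their place the peaks were moved along each chromosome by 100 random circular shifts, a choice made after the data were examined. Recurrence over the 3 pairs was set beside the overlap of independent lists. The direction over the pairs has an exact two-sided sign test, whose smallest possible p is 0.25.

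The rule for named peaks was set before the data were examined. It took, for each pair, the 5 knockdown-only and the 5 control-only peaks with the highest fold in their own list and the 5 widest. Across pairs it took up to 10 regions that were knockdown-only, or control-only, in all 3 pairs, by mean rank of fold. It also took the 5 best-ranked regions in both Kdm5b lists. The text gives a selection of these and counts over the rest. No gene annotation of mm9 was used here, so peaks are named by position, promoters and gene bodies were not told apart, and the gene lists fixed beforehand were not looked up. All positions are mm9 and count from 1.

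The alternatives were peaks with −log10 q of at least 5 or 10, the same number of top peaks in both lists, merging of peaks within 1000 bp, autosomes only, other rules of overlap, other distances and other sets of Kdm5b peaks. They were fixed before the data were examined. Thinning of the knockdown reads to the control depth, in 20 random draws, was added afterwards. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Reads and signal tracks were not analysed here, so levels at a given site were not compared between conditions.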

Results

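H3K4me3 was mapped in WW6 mouse embryonic stem cells, a line of mixed strain background grown without feeder cells, after knockdown of Kdm5b and in control cells. Each condition had 1 H3K4me3 library and 1 peak list. The control library was the shallower, at an estimated 4.19 reads per kb against 8.63 in the knockdown library. A median peak summit held 12 reads in the control list and 17 in the knockdown list. The authors also deposited control and knockdown H3K4me3 lists remade from 2 other data sets, named Kidder and Schmitz here, and a Kdm5b list from each. The amount of Kdm5b left after knockdown was not analysed here.

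The comparison of this study asked where H3K4me3 lies in cells depleted of Kdm5b. The knockdown list held 9573 peaks and the control list 6071, a ratio of 1.58. Peaks covered 3.19 Mb in knockdown cells and 1.85 Mb in control cells, a ratio of 1.72. Peaks were narrow in both lists, with a median width of 273 bp after knockdown and 254 bp in the control. The knockdown library was estimated at 2.06 times the depth of the control library. The direction turned at stricter thresholds: among peaks with −log10 q of at least 5, the control list held 3829 and the knockdown list 2614, a ratio of 0.683, and at 10 or more they held 841 and 121. With the knockdown reads thinned to the control depth, an alternative added after the data were seen, the ratio was 1.09 at the lowest p of the control list and 0.754 at its 5th percentile. Only called knockdown peaks were thinned, so their number could only fall.

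Most control sites were found again after knockdown. Of the 6071 control peaks, 3766 overlapped a knockdown peak, which is 62.0% (95% exact Clopper-Pearson interval 60.8 to 63.3). The knockdown list had 5759 peaks of its own, 60.2% (59.2 to 61.1) of that list, and the control list had 2305 of its own. Peaks in 1 list ranked lower by fold than shared peaks. The median knockdown-only peak stood at percentile 44.3 of its list and the median shared peak at 59.7, and in the control list these percentiles were 45.7 and 52.6. Of control peaks in the highest decile of fold, 76.5% (73.0 to 79.7) were shared, against 51.1% (47.0 to 55.2) in decile 3, the least shared. In the knockdown list the same shares were 66.7% (63.6 to 69.7) and 29.2% (26.3 to 32.2). Sharing did not rise steadily with fold. In decile 1, the lowest, it was 64.5% in the control list and 39.6% in the knockdown list. The control share fell to 27.7% when both lists were restricted to −log10 q of at least 5 and to 3.45% at 10 or more, where the knockdown list held 121 peaks. Searched in the full knockdown list, 654 of the 841 control peaks at 10 or more were found, or 77.8%.

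**Figure D1:**
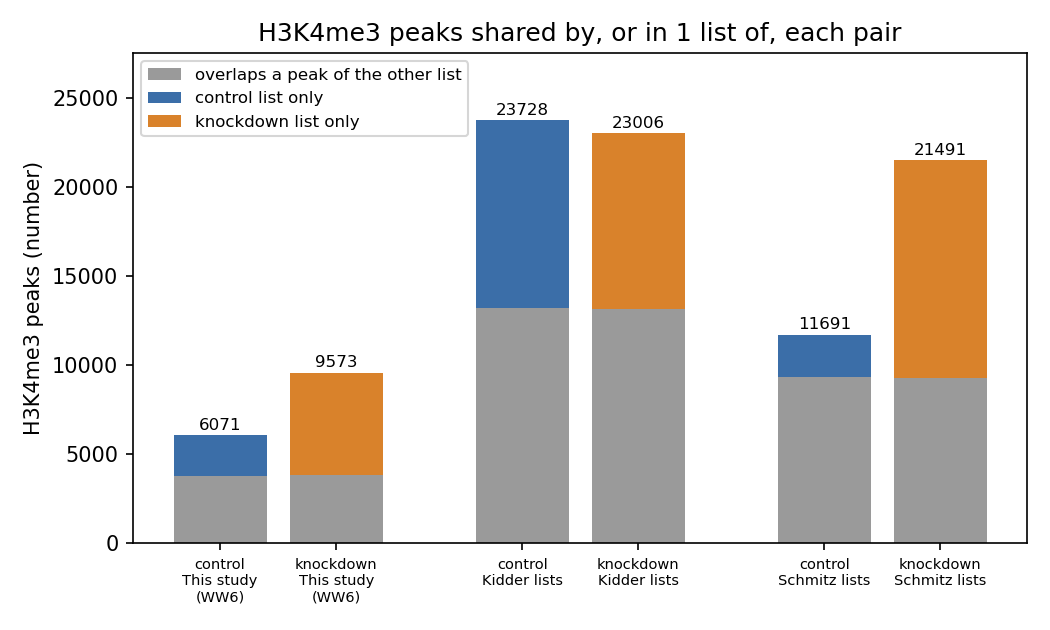
Number of H3K4me3 peaks (vertical axis) in the control and knockdown list of each pair, split into peaks that overlap a peak of the other list (grey) and peaks in the control list only (blue) or the knockdown list only (orange). The knockdown list was the longer in this study (9573 against 6071) and in the Schmitz data (21491 against 11691), and slightly the shorter in the Kidder data (23006 against 23728).

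The knockdown-only peak with the highest fold in this study lay on chromosome 15 at 103103452 to 103103999, with a fold of 10.9. It was followed by peaks on chromosome 13 at 24893080 to 24893315, on chromosome 17 at 46909823 to 46910520 and on chromosome 6 at 29558826 to 29559551. All 4 regions had a peak in both the Kidder and the Schmitz control list. The fifth, on chromosome 1 at 74552625 to 74552850, was in none of the other H3K4me3 lists. The control-only peak with the highest fold, 15.6, lay on chromosome 5 at 140895310 to 140895764. The next stood on chromosome 11 at 104303827 to 104304124 and on chromosome 4 at 15885099 to 15885319. All 3 also had a peak in the Schmitz knockdown list. In the Kidder data all 3 had a peak in the control list, but only the peak on chromosome 11 had one in the knockdown list. The widest knockdown-only peak spanned 1357 bp on chromosome 19, at 32832708 to 32834064, and the widest control-only peak 901 bp on chromosome 12, at 11272970 to 11273870.

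Many peaks in 1 list lay beside a peak of the other list. Of the 5759 knockdown-only peaks, 43.2% (41.9 to 44.5) were within 5000 bp of a control peak. Of the 2305 control-only peaks, 50.7% (48.7 to 52.8) were within that distance of a knockdown peak. Peaks moved at random along the placed chromosomes gave a mean of 2.15% for the knockdown-only peaks and 2.75% for the control-only peaks. The highest of 100 such shifts gave 2.73% and 3.53%. The shifts do not keep the peaks of both lists in the same parts of the genome. An observed share above theirs was therefore to be foreseen, and how far clustering of peaks accounts for it was not tested. Within 2000 bp the knockdown-only share was still 40.9%. At −log10 q of at least 10 in both lists it was 7.69%, or 7 of 91 peaks.

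Few H3K4me3 peaks of this study coincided with Kdm5b peaks, whether or not they were shared. Of the knockdown-only peaks, 26 of 5759 overlapped a peak in either Kdm5b list, which is 0.451% (0.295 to 0.661). For control-only peaks it was 9 of 2305, or 0.390% (0.179 to 0.740), and for peaks shared by both lists 41 of 3814, or 1.07% (0.773 to 1.46). Random lists from the knockdown list matched on fold had a median of 0.695%, and the knockdown-only share stood at percentile 0.015 of them. Lists matched on peak width placed it at percentile 0.755, and the control-only share stood at percentile 0.75 of its own lists matched on fold. By Kdm5b list the control-only peaks split, with 1 at a Kidder Kdm5b peak (percentile 0) and 8 at a Schmitz Kdm5b peak (percentile 97.7, or 85.8 matched on width). Both Kdm5b lists together covered 0.758% of the control H3K4me3 peaks. With the Schmitz Kdm5b list alone the knockdown-only share was 0.0868%, at percentile 31.0 of random lists, and with regions in both Kdm5b lists 0.0347%, at percentile 56.1.

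The same contrast in the authors' deposited Kidder lists gave nearly equal numbers, with 23006 peaks after knockdown and 23728 in the control, a ratio of 0.970. Covered length was 11.5 Mb and 11.2 Mb. The knockdown-only peaks numbered 9852, or 42.8% (42.2 to 43.5) of their list, and the control-only peaks 10542. Of the knockdown-only peaks, 61.8% (60.8 to 62.7) lay within 5000 bp of a control peak. The highest-ranked knockdown-only peaks of the authors' deposited Kidder lists were on chromosome 6 at 47785961 to 47786743 and on chromosome 4 at 98399768 to 98400276. The former had a peak in both lists of this study, and the latter in none of the other H3K4me3 lists. Kdm5b peaks overlapped 6 knockdown-only peaks, or 0.0609% (0.0224 to 0.133), and 42 control-only peaks, or 0.398% (0.287 to 0.538). These libraries were shallow, at an estimated 0.190 reads per kb in the control and 0.474 after knockdown, with median summits of 4 and 6 reads. The direction turned at −log10 q of at least 5, where the ratio was 1.17.

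In the authors' deposited Schmitz lists the knockdown list was the longer, with 21491 peaks against 11691, a ratio of 1.84. Of the control peaks, 79.5% (78.8 to 80.3) were shared. The knockdown-only peaks numbered 12210, or 56.8% (56.1 to 57.5) of their list, and the control-only peaks 2391. Knockdown-only peaks were less often beside a control peak than in the other pairs, 23.1% (22.4 to 23.9) within 5000 bp. They ranked low by fold, with a median at percentile 36.0 of the knockdown list, against 69.9 for shared peaks. The leading knockdown-only peak in the authors' deposited Schmitz lists was on chromosome 8 at 122638008 to 122638407, and the leading control-only peak on chromosome 7 at 31348395 to 31348653. Kdm5b peaks overlapped 61 of the 12210 knockdown-only peaks (interval 0.382% to 0.641%) and 244 of 9281 shared peaks, or 2.63% (2.31 to 2.98). The knockdown library was estimated at 0.513 times the depth of the control library, 1.42 against 2.76 reads per kb. The ratio of peak numbers stayed above 1 under each alternative run for it, between 1.62 and 2.61.

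**Figure D2:**
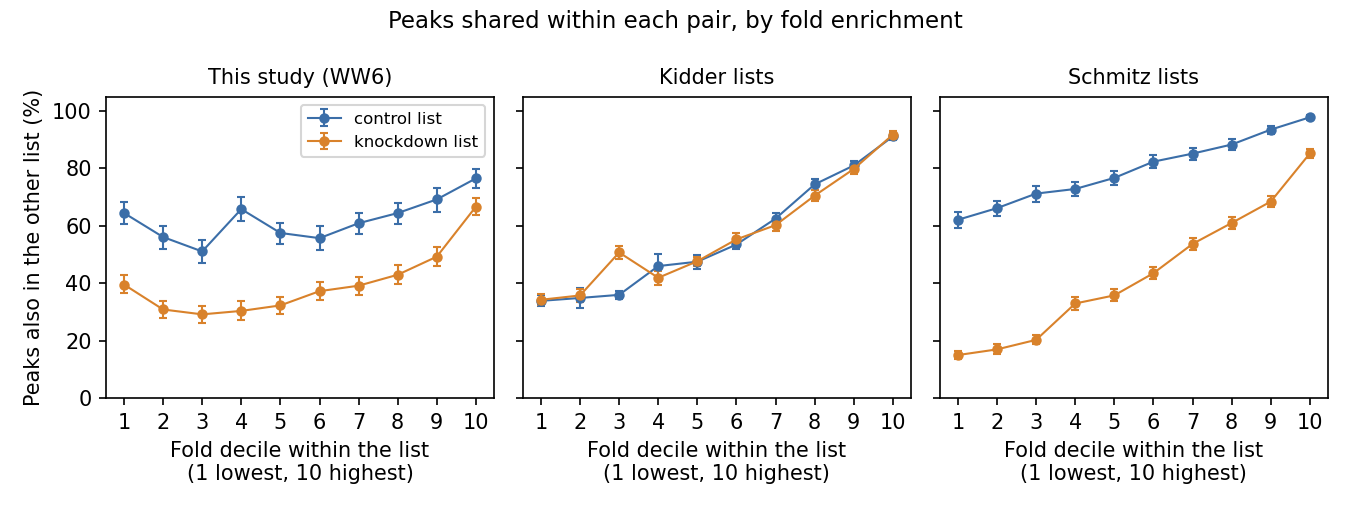
Share of peaks that overlap a peak of the other list of the pair (%, vertical axis) by decile of fold enrichment within the list (horizontal axis, 1 lowest to 10 highest), for control (blue) and knockdown (orange) lists. Error bars are 95% exact Clopper-Pearson intervals. In each of the 6 lists the highest decile had the highest share, from 66.7% in the knockdown list of this study to 97.8% in the Schmitz control list.

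Across the 3 pairs, 2 had more peaks after knockdown than in the control (exact two-sided sign test, p = 1, smallest possible p 0.25). The 6 lists merged into 38345 regions, of which 2754 had a peak in every list. A common set of 3887 regions had a peak in all 3 control lists. Of these, 3160 (81.3%) had a peak after knockdown in this study, 3547 (91.3%) in the Kidder data and 3596 (92.5%) in the Schmitz data.

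Most sites seen in this study only after knockdown were H3K4me3 sites in control cells of the other data. Of the 5759 knockdown-only peaks, 4723 overlapped a peak in the Kidder or Schmitz control list, which is 82.0% (81.0 to 83.0), and 94.5% (93.9 to 95.1) a peak in any of the 4 other H3K4me3 lists. The mirror image held for control-only peaks, of which 90.4% (89.1 to 91.6) overlapped a peak in either other knockdown list. Control-only peaks of this study were found more often in the Schmitz knockdown list, 77.0% (75.3 to 78.8), than in the Schmitz control list, 53.1% (51.1 to 55.2). In the Kidder data it was the opposite, 56.1% (54.0 to 58.1) in the knockdown list and 69.0% (67.1 to 70.9) in the control list. Knockdown-only peaks of the other data were found less often in the other control lists, 9.70% (9.13 to 10.3) for Kidder and 40.1% (39.2 to 40.9) for Schmitz. The other lists are longer than those of this study, the Schmitz knockdown list is 1.84 times as long as its control list, and the shares were not adjusted for length.

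**Figure D3:**
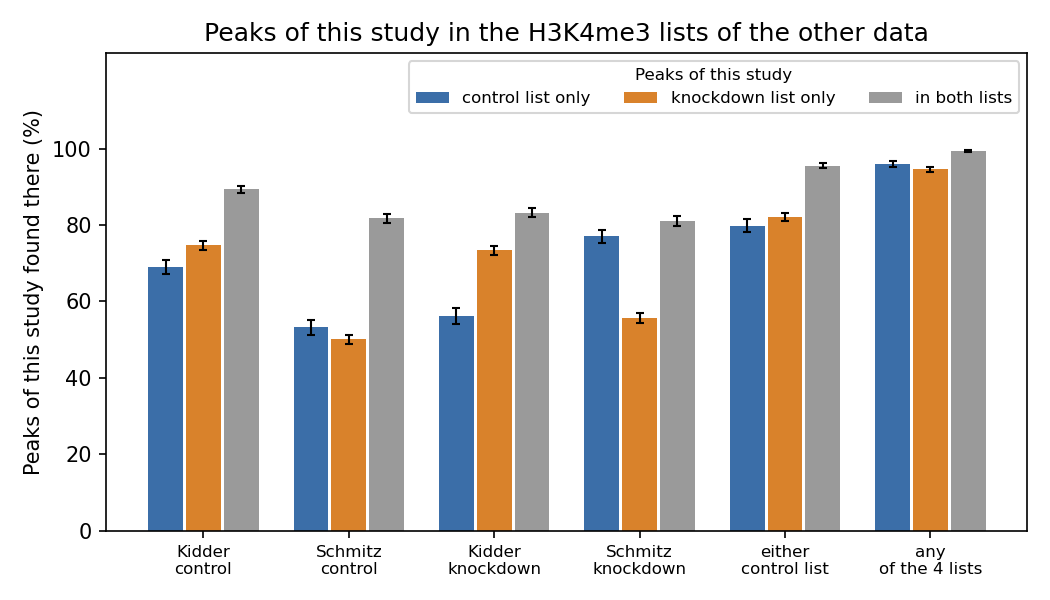
Share (%, vertical axis) of this study's control-only (blue), knockdown-only (orange) and shared (grey) peaks that overlap a peak in each H3K4me3 list of the other data, in either of their control lists or in any of the 4 lists (horizontal axis). Error bars are 95% exact Clopper-Pearson intervals. Shared peaks were found most often, 99.4% in any of the 4 lists, and 82.0% of the knockdown-only peaks were in either control list.

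Regions knockdown-only in all 3 pairs numbered 97. Independent lists over the whole union would share 275, and independent lists among the 7498 regions with a peak in each pair 30.1. Regions control-only in all 3 pairs numbered 16, beside 14.2 and 9.71. The best-ranked recurrent knockdown-only regions were on chromosome 4 at 151460968 to 151461895, chromosome 8 at 87607191 to 87607887 and chromosome 10 at 81022237 to 81023520. The best-ranked recurrent control-only regions were on chromosome X at 12859169 to 12860132 and chromosome 2 at 176817290 to 176817826. None of the 10 named regions of either kind overlapped a Kdm5b peak. Of this study's knockdown-only peaks, 10.5% (9.72 to 11.3) overlapped a Kidder knockdown-only peak and 15.9% (14.9 to 16.8) a Schmitz one, where random lists matched on fold had medians of 8.58% and 14.4%. Both shares stood at percentile 100 of the 10000 random lists. Those lists also held peaks shared within this study, which lay more often in the other control lists. In the Kidder control list they were 89.3% against 74.7% of knockdown-only peaks, and in the Schmitz control list 81.7% against 50.0%. A higher knockdown-only share can therefore arise without recurrence. Overlaps in opposite directions were counted among regions with a peak in both pairs, beside those of independent lists. Regions knockdown-only in this study and control-only in the Schmitz data numbered 303 beside 229, and the reverse 457 beside 261. With the Kidder data in place of Schmitz these were 523 beside 446 and 119 beside 98.8. Regions knockdown-only in the Kidder data and control-only in the Schmitz data numbered 120 beside 140, and the reverse 1627 beside 983. In the same direction, regions knockdown-only in both pairs numbered 433 beside 285 for this study and Kidder, and 771 beside 601 for this study and Schmitz. For Kidder and Schmitz they numbered 980 beside 571. Regions control-only in both pairs numbered 281 beside 155 for this study and Kidder. They numbered 79 beside 99.5 for this study and Schmitz, and 197 beside 240 for Kidder and Schmitz. At −log10 q of at least 10 in both lists of each pair, 2 regions were knockdown-only and 23 control-only in all 3 pairs.

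The Kdm5b lists were short, and partly shared between laboratories. The Kidder list held 743 peaks and the Schmitz list 253, and 184 of the Schmitz peaks, 72.7% (66.8 to 78.1), overlapped a Kidder peak. In the opposite direction it was 188 of 743, or 25.3% (22.2 to 28.6). Both lists had 183 regions in common. The best-ranked were on chromosome X at 166527028 to 166527645, chromosome 12 at 94815290 to 94815801, chromosome 14 at 86598666 to 86599089, chromosome Y at 2652067 to 2652450 and chromosome 16 at 93789293 to 93789770. All 5 had a peak in both Schmitz H3K4me3 lists, and none in either list of this study. Of the 183 common regions, 135 had a peak in the Schmitz H3K4me3 control list, 73.8% (66.8 to 80.0), and 152 in the Schmitz knockdown list, 83.1% (76.8 to 88.2). Only 2 had one in the control list of this study, 12 in the Kidder control list and 0 in the Kidder knockdown list, which allows a share of up to 2.00%. In the Kidder Kdm5b list 117 peaks were on the unassembled sequence that mm9 assigns to no chromosome and 5 on mitochondrial DNA. None of the 3 Schmitz lists had a peak on either, and whether their reads were aligned to the same sequences is not given in the sources used here.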

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

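Thinning the reads, the depth ratio of the Schmitz pair and the recount without chromosome X were chosen after the results they bear on were seen. The overlap with Kdm5b sites was planned, but its use as a test of the excess of peaks was chosen afterwards. The pairs differed in the direction of their peak numbers. The Kidder ratio of knockdown to control was 0.970, whereas it was 1.58 in this study and 1.84 in the Schmitz data. The difference between the pairs was not tested, since each pair has 1 list per condition.

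In this study the longer list came from the deeper library, by 2.06 times. After the scaling by the peak caller the difference was smaller, with backgrounds of 5.58 reads per kb in the knockdown and 4.14 in the control. With the knockdown summit reads thinned to the control depth, the ratio of peak numbers was 1.09 at the lowest p of the control list. It was 0.754 at the 5th percentile, against 1.58 in the full lists. Only peaks already called were thinned, so the number of knockdown peaks could only fall. Without thinning, the ratio was already 0.683 among peaks with −log10 q of at least 5. Greater depth is a candidate explanation for the excess in number, which the thinning cannot decide. The knockdown list also had lower folds. Its median was 5.64 against 6.93 in the control list, and its highest 11.3 against 18.9. Whether the libraries differed in enrichment was not tested. In the Kidder pair the knockdown library was estimated at 2.5 times as deep, yet the ratio of peak numbers was 0.970. Recovery of reads was not tested at the Kidder values, and this ratio was 1.17 at −log10 q of at least 5. The Kidder pair therefore does not decide whether depth sets the ratio. Nor can the thinning settle which sites differ. After it, 65.2% of the knockdown-only peaks were still called at the lowest p and 40.6% at the 5th percentile. Of all 9573 knockdown peaks, a mean of 6619 and 4380 were still called, so the knockdown-only peaks did not stand apart. An effect of Kdm5b loss at its own sites stays open, with the knockdown-only overlap at percentile 0.015 of matched random lists, because the Kdm5b lists cover only 0.758% of the control peaks.

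In the Schmitz data the longer knockdown list came from the shallower library, at 0.513 times the control depth, which argues against greater depth as its source. An effect of lower depth was not tested and stays open. Both libraries were scaled to the same background, and the lowest summit held 16 reads in the control list and 5 in the knockdown list. A mixture of chromosome shares was then fitted, in which 0 is the distribution of the regions in all 3 control lists and 1 is the span of each chromosome. The Schmitz knockdown-only peaks had a span weight of 0.702 (bootstrap interval 0.660 to 0.749), and 0.618 (0.555 to 0.682) without chromosome X, against 0.409 (0.306 to 0.508) for the Schmitz control-only peaks, 0.115 for shared Schmitz peaks and 0.0134 for the knockdown-only peaks of this study. Background regions called as peaks are a hypothesis for this. The low weight of shared Schmitz peaks is partly built in, because 3596 of the 3887 reference regions had a Schmitz knockdown peak. Of the Schmitz knockdown-only peaks, 52.8% (51.9 to 53.7) overlapped an H3K4me3 peak of the other data, against 90.1% of the control-only peaks. The ratio of peak numbers was 2.61 at −log10 q of at least 10, where weak calls drop out. Both values limit how much of the excess such background can explain. Weak H3K4me3 outside the common sites would spread alike and stays open, as does an effect of the knockdown, which 1 library per condition leaves untested.

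Chromosome X went a different way in the Schmitz pair. Its share of peaks was 1.80% in the control and 3.49% after knockdown, a ratio of 1.94, whereas it went from 0.758% to 0.345% in this study, a ratio of 0.455, and from 2.93% to 1.89% in the Kidder data, a ratio of 0.646. This difference was not tested either.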

How the results depend on the processing

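The thinning of reads was added after the data were seen, and the other alternatives were planned. Among results that answer a comparison, 22 alternative values stayed within the main value's interval (counts within 1.5 times), 65 moved further without reversing, and 4 reversed. Of the other results, 24 stayed, 45 moved and 3 reversed, where covered length and percentiles, which have no interval, count as moved. The cause was not tested unless stated. Values below are for this study unless named otherwise. Promoter windows were not run, because no mm9 annotation was used here. Equal numbers of top peaks fix the ratio of peak numbers at 1, and merged regions always hold their own peaks, so the stricter overlap gives no count of recurrent regions. No paired analysis was possible because each condition of this study has 1 library, and over the 3 pairs of lists the sign test alone was run. Summits held few reads in the Kidder data, with a median of 4 in the control list, and the effect of depth there was not tested.

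At −log10 q of at least 5, the ratio of peak numbers reversed to 0.683 and that of covered length to 0.880, and the Kidder ratio of peak numbers reversed to 1.17. Control peaks shared were 27.7%, knockdown-only peaks near a control peak 29.8% and at a Kdm5b peak 0.771%. Knockdown-only shares were 49.9% (Kidder) and 55.5% (Schmitz), and the Schmitz ratio was 1.62. Recurrent knockdown-only regions numbered 37 and control-only ones 26.

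At 10 or more, the ratio of peak numbers reversed to 0.144, that of covered length to 0.194 and the Kidder covered length to 0.809. Kidder and Schmitz ratios of peak numbers were 0.781 and 2.61. Control peaks shared were 3.45%. Knockdown-only shares were 75.2%, 56.3% (Kidder) and 75.2% (Schmitz). Of the knockdown-only peaks, 7.69% were near a control peak, 0% at a Kdm5b peak (0 of 91) and 72.5% in another control list. Recurrent knockdown-only regions numbered 2.

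With equal numbers of top peaks, control peaks shared were 46.2%, and knockdown-only shares 54.4%, 43.6% (Kidder) and 39.6% (Schmitz). Near a control peak were 41.7% of the knockdown-only peaks, and in another control list 84.9%. Recurrent regions numbered 34 of each kind, and 58.5% of Schmitz Kdm5b peaks were in the Kidder list.

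With peaks within 1000 bp merged, ratios of peak numbers were 1.39, 0.942 (Kidder) and 1.79 (Schmitz). Control peaks shared were 65.7%, and knockdown-only shares 52.5%, 37.4% (Kidder) and 51.4% (Schmitz). Of the knockdown-only peaks 85.6% were in another control list. Recurrent regions numbered 63 knockdown-only and 6 control-only, and 78.8% of Schmitz Kdm5b peaks were in the Kidder list. On autosomes the Schmitz knockdown-only share was 55.8%.

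With an overlap of 50% of the shorter peak, control peaks shared were 54.1%, knockdown-only shares 65.8%, 50.1% (Kidder) and 58.9% (Schmitz), near a control peak 48.1% and in another control list 75.6%. With peaks within 1000 bp counted as shared, these were 79.6%, 38.3%, 25.3% (Kidder), 45.7% (Schmitz), 10.8% and 93.5%, and 5 regions were control-only in all pairs; the rule itself takes the nearest peaks out of the knockdown-only set.

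With peaks in 1 list held to −log10 q of at least 10 and searched in the full other list, control peaks shared were 77.8%, knockdown-only shares 24.8%, 11.5% (Kidder) and 27.0% (Schmitz), in another control list 93.3% and at a Kdm5b peak 0% (0 of 30). Recurrent regions were 0 of either kind.

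Within 2000 bp and 10000 bp of a control peak lay 40.9% and 46.4% of the knockdown-only peaks, where a wider window can only raise the share. With the Schmitz Kdm5b list alone 0.0868% and with regions in both Kdm5b lists 0.0347% of them were at a Kdm5b peak. Thinned to the control depth, the ratio of peak numbers was 1.09 at the lowest p and reversed to 0.754 at the 5th percentile p.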

Other observations

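The test against promoters common to embryonic stem cells was chosen after the overlap of the Kdm5b and H3K4me3 lists was seen, and the tests of summit distance were not. The 183 regions in both Kdm5b lists were mostly H3K4me3 peaks in the Schmitz data, 135 in the control and 152 after knockdown, yet 168 of them (91.8%) had no peak in any H3K4me3 list of this study or of Kidder.

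Kdm5b bound at H3K4me3 promoters common to embryonic stem cells is argued against. Of the 135 regions with a Schmitz control peak only 4, or 2.96% (0.813 to 7.41), had a Kidder control peak, while 79.0% of all Schmitz control peaks did. In the Schmitz data the summits of the Kdm5b and H3K4me3 control peaks at these regions lay a median of 5 bp apart (4 bp for the knockdown), against 131 bp over the 104 Kidder Kdm5b peaks that overlap a Kidder control peak, a wider set of regions. The median summit held 4 reads in the Kidder control list and 33 in the Schmitz control list, and their narrowest peaks were 267 bp and 149 bp. The effect of these differences on summit distance was not tested. A candidate explanation, as a hypothesis, is that the regions in both Kdm5b lists have high signal in every Schmitz library, whatever the antibody. That hypothesis leaves the Kidder Kdm5b peaks at the same regions unaccounted for, so Kdm5b bound there in both data sets, with H3K4me3 peaks mainly in the Schmitz data, stays open.

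The span of chromosomes also carried weight in the Kidder control-only peaks, 0.637 (0.590 to 0.689), but little in the Kidder knockdown-only peaks, 0.215 (0.172 to 0.263). In this study the control-only peaks had a weight of 0.281 (0.195 to 0.372).

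On chromosome 1 the knockdown-only peak at 74552625 to 74552850 lay beside a region at 74553256 to 74554127 that was control-only in all 3 pairs. Both are named by the rule set before the data were examined, and their closeness was noticed afterwards.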
